A study of Saccharomyces cerevisiae with 12 samples.

How the data were processed

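Total RNA was taken from mid-exponential cultures of D452-2 yeast that carried pRS316 with cdt-1 in its endogenous codons (NC) or codon-optimized (OPT), and libraries were made with a TruSeq RNA kit, per the labels' protocols. The design text calls the samples biological replicates. The 6 mRNA libraries, 3 NC and 3 OPT, were matched to their samples by library name. The 6 ribosome footprint libraries of the series were not analysed here, so the planned comparisons of footprints and of translational efficiency were not made.

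The authors deposited 1 table of normalized RPKM values per gene and library, per the file headers, with values rounded to 2 decimals. The submitters' processing notes name the genome build R64 and the tools CASAVA 1.8.0, Bowtie and TopHat. How reads were counted, whether strand was used, how multiply mapping reads were treated and how the RPKM were normalized is not given in the sources used here. Each library's RPKM add up to just under 1000000, so they behave as shares of a total, and a rise of a few abundant transcripts lowers all others. Reads from near-identical copies and from overlapping or antisense genes cannot be told apart and are marked as uncertain.

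The table held 6347 features after 3 emptied lines and 1 repeated row of ZWF1, whose values were shifted by a column, were left out. Of these, 6008 matched a locus of the RefSeq annotation of R64, 5887 of them protein-coding. Coordinates are RefSeq's, since the table has none, and give the gene's annotated span. Depth was estimated from the low values: multiplied by RefSeq gene length, values worth up to 20 reads were whole multiples of one step per library within 0.15 of a read in 98.8 to 100.0% of 83 to 115 values, against 23.7 to 27.4% at wrong steps. The step put depth at 23500000 to 43300000 reads. These estimates were used to describe depth only, and no test on counts was run. At that depth 1 read in a gene of 1000 nucleotides is worth 0.0222 to 0.0411 RPKM.

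Values were tested as log2(RPKM + 1) with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with a trend, two-sided), NC against OPT without covariates, over features with a mean of at least 1 RPKM in the 6 libraries. Fold changes are on that scale, which understates changes of low genes. P-values were adjusted by the Benjamini-Hochberg method, and an adjusted p under 0.05 was a call. The 2 cdt-1 rows stayed in the fit but were not counted among calls. Gene lists were tested with limma's camera at a preset correlation of 0.01, adjusted over the 39 of 40 lists with at least 5 measured members. The 2 groups of genes added after the data were seen were tested the same way, adjusted over both, without the members that the text names or that had been seen beforehand. Single values were compared with exact permutation tests. Tables were prepared with Python 3.11.15, numpy 2.4.6 and pandas 2.3.3, and figures with matplotlib 3.10.9.

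The lists, the rule for named genes, the tests and all alternatives but one were fixed before the data were examined. Named genes were, among called genes with no overlap between groups and a mean of at least 5 RPKM, the 10 largest rises and 10 largest falls, in which the OPT and NC rows of cdt-1 themselves took 1 place each, with up to 4 called members of each list by size of change or, where none was called, the 2 most abundant. URA3, HIS3, LEU2, HAC1, KAR2, cdt-1 and the mean of ribosomal protein genes were always included. Some of the genes that this rule named are not reported here. Some lists had faults that were left as fixed: the cell wall list holds MLP1 by its alias, the pattern for cytosolic ribosomal proteins takes RPP1, a ribonuclease P subunit that fell, and the Ty pattern takes other small reading frames.

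The pipeline was tested on 10 simulated sets of the mRNA comparison, each with 5970 features on average at the measured means and spreads, of which 200 were changed. It recovered 88.8% of changes of 1 and 60.4% of changes of 0.5 on the log2 scale, and 4.7% of its calls were false. The noise was drawn independently for each feature and with the same spread in both strains. In the data, features vary together and the NC libraries spread more, so these shares need not hold for the data.

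Alternatives were a pseudocount of 0.1, no filter, a filter of 10 RPKM, quantile normalization, median centring, a common prior variance, arrayWeights, leaving out each library in turn, and for lists an estimated correlation and fry. A fit to protein-coding genes only was added after the data were seen.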

Results

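The series compared 2 strains of the budding yeast *Saccharomyces cerevisiae*, both built in the laboratory strain D452-2, that carried the plasmid pRS316 with a gene for cdt-1, a cellodextrin transporter of the filamentous fungus *Neurospora crassa* and a protein that spans the membrane many times. In one strain, called NC, the transgene kept its endogenous codons. In the other, called OPT, its codons had been optimized for the host. Cells of both strains were taken in mid-exponential growth, and the study's title places the question in the control of membrane protein synthesis by translation elongation. Of the 12 libraries in the series, the 6 mRNA libraries are described here, 3 biological replicates of NC and 3 of OPT. The 6 libraries of ribosome-protected fragments were not analysed here, so every value below is an mRNA level and none is a translation rate.

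Levels were given as normalized RPKM, with each library adding up to 999285 to 999421. The low values of each library were whole multiples of a fixed step once multiplied by gene length, and that step corresponds to an estimated depth of 30500000, 23500000 and 26100000 reads in NC replicates 1, 2 and 3 and of 43300000, 34000000 and 33500000 reads in OPT replicates 1, 2 and 3. Between OPT libraries the Pearson correlation of log2 values across genes was 0.991 to 0.996. NC replicates 1 and 2 correlated at 0.992, whereas NC replicate 3 correlated at 0.979 and 0.985 with the other 2. On the first principal component, with 63.6% of the variance, the 3 NC libraries lay between -18.0 and -12.6 and the 3 OPT libraries between 14.5 and 17.1. The second, with 19.7%, set NC replicate 3 at -16.9 against 12.4 and 5.68 for NC replicates 1 and 2. Features with ribosomal RNA names made up 0.352, 0.387 and 0.568% of the total in NC and 1.32, 1.56 and 0.475% in OPT.

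The mRNA of the transgene itself stood at a similar level in both strains. The row for the version with endogenous codons stood at 518, 506 and 567 RPKM in the 3 NC libraries and was listed at 0 in all 3 OPT libraries, and the row for the optimized version stood at 420, 557 and 530 RPKM in OPT and at 0 in NC. Summed over both rows, cdt-1 mRNA came to 530 ± 32.7 RPKM in NC and 502 ± 72.2 in OPT (SD, n = 3). The log2 difference, OPT minus NC, was -0.09 with a standard error of 0.12 (limma adjusted p = 0.648), and a two-sided exact permutation test of the 6 values gave p = 0.8, where 0.1 is the smallest p that 3 against 3 can give. The difference was thus smaller than the spread between replicates, and it was 0.04, again short of the threshold, without OPT replicate 1. Both rows are described as carrying the same GFP tag, and the exact zeros are no independent check of the labels, because how reads from shared sequence were assigned is not given in the sources used here.

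**Figure D1:**
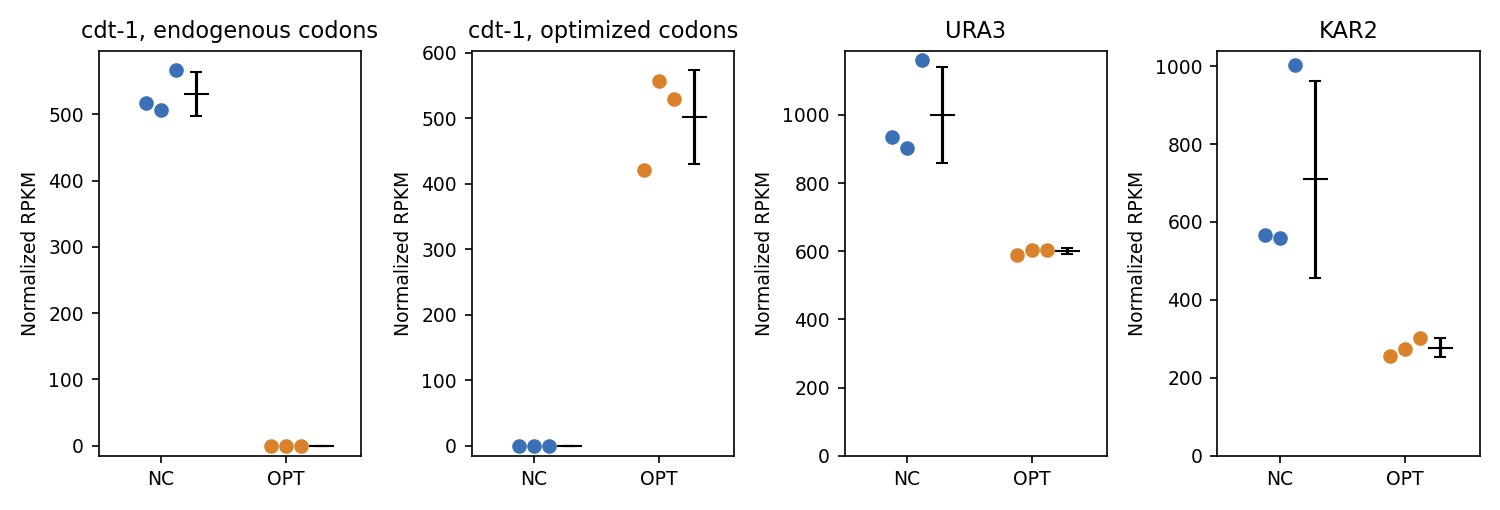
Normalized RPKM (y axis, linear) of the 2 cdt-1 rows, of URA3 and of KAR2 in each NC library (blue) and OPT library (orange), with the mean and SD of the 3 libraries in black. Each cdt-1 row is listed at 0 in the other strain, URA3 lay at 999 ± 140 in NC and 600 ± 8.58 in OPT, and KAR2 was highest in NC replicate 3.

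The plasmid's selection marker was lower in OPT. URA3, which encodes an enzyme of pyrimidine synthesis and is the marker of pRS316, fell from 999 ± 140 to 600 ± 8.58 RPKM (log2 fold change -0.73, standard error 0.11, adjusted p = 0.00729). Its values come from a single row, matched to the chromosomal locus. Reads of the plasmid copy and of any chromosomal copy therefore cannot be told apart. HIS3 and LEU2 are genes of histidine and leucine synthesis and auxotrophic markers of the parent strain. HIS3 fell from 196 ± 32.0 to 132 ± 8.55 (adjusted p = 0.0272), a call that ended with quantile normalization and when NC replicate 1 or 2 or any OPT replicate was left out (adjusted p up to 0.1). LEU2 stood at 120 ± 26.8 and 147 ± 11.5, which did not pass the test (adjusted p = 0.23).

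In the rest of the transcriptome, genes of sulfate assimilation, and THI4 and other genes of thiamine synthesis, stood far higher in OPT than in NC, and genes for protein folding in the endoplasmic reticulum (ER) stood lower. Of 5982 yeast features tested with limma, 1145 differed at an adjusted p under 0.05, of which 322 were higher and 823 lower in OPT. Changes of 2-fold or more were mostly rises, with 85 features higher and 22 lower. The groups did not overlap in 2432 features, or 40.7% against the 10% that chance gives on average for 3 against 3. Features vary together across libraries, so the share of a single split can lie far from that average, and the comparison does not settle chance. The balance of the calls depended on the scaling: 71.9% of the calls were lower with the deposited scale, 58.9% with quantile normalization, and 51.0%, with 471 higher and 491 lower, once the library medians were set equal, although the median shift of all features was only -0.06. Without NC replicate 3 the count rose to 1953, and it was 483, 361 and 525 without OPT replicate 1, 2 and 3.

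The largest rises were in 9 yeast genes from a few pathways. MET3, which encodes ATP sulfurylase (chromosome X, 456239 to 457774 in build R64), rose from 53.4 ± 14.9 to 878 ± 85.1 RPKM, a log2 fold change of 4.05 with a standard error of 0.20 (adjusted p = 0.000146). MET14, the kinase of the next step (chromosome XI, 438777 to 439385), rose from 122 ± 28.3 to 1321 ± 177, and SUL2, a sulfate permease, from 34.3 ± 7.12 to 266 ± 35.6. THI4, an abundant enzyme that makes the thiazole moiety of thiamine (chromosome VII, 780399 to 781379), rose from 463 ± 196 to 6233 ± 237, a log2 fold change of 3.86. THI13, THI11 and THI5, which make the other moiety of thiamine, rose by 3.55, 3.27 and 2.98 on the log2 scale, but they are near-identical copies whose separate values are uncertain. PDC5, a pyruvate decarboxylase isozyme, rose from 137 ± 69.8 to 1341 ± 61.4, and GRE1, a hydrophilin made under osmotic stress, from 72.4 ± 22.7 to 534 ± 22.6.

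The largest falls were smaller in size. SIL1, the nucleotide exchange factor of the ER chaperone Kar2 (chromosome XV, 266264 to 267529), fell from 99.6 ± 42.1 to 31.7 ± 0.987 RPKM (log2 fold change -1.55, standard error 0.25, adjusted p = 0.00949). ARG1, an enzyme of arginine synthesis, fell from 2170 ± 208 to 860 ± 71.2, FRM2, a nitroreductase, from 26.0 ± 1.93 to 10.2 ± 0.416, and MCD4, an enzyme of GPI anchor synthesis, from 133 ± 16.7 to 55.9 ± 2.77. EUG1, a protein disulfide isomerase, fell from 64.3 ± 17.6 to 26.1 ± 1.89. KAR2 is taken up with the ER genes. FRE4, a ferric reductase (log2 fold change -1.35), CUP1-2, a copper metallothionein (-1.25), and YOL155W-A (-1.19) also ranked here, but each of these 3 calls ended with equal library medians and when any OPT library, or 1 of the NC libraries, was left out, with adjusted p up to 0.139, 0.113 and 0.121. CUP1-2 has a near-identical copy and overlaps the noncoding RUF5-2, so its value is uncertain.

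Transcripts for folding and the unfolded protein response in the ER were lower in OPT across almost the whole list. Of 18 tested genes, 15 fell and none rose (16 fell when adjusted over the list alone), with a median log2 fold change of -0.72. KAR2, the ER Hsp70 chaperone (chromosome X, 381327 to 383375), fell from 710 ± 253 to 277 ± 23.7 RPKM, a log2 fold change of -1.30 with a standard error of 0.23. ERO1, the ER thiol oxidase, fell from 149 ± 42.8 to 68.6 ± 2.18, and HAC1, whose mRNA encodes the transcription factor of the unfolded protein response, from 465 ± 99.2 to 281 ± 9.88. Camera gave the list an adjusted p of 3.42e-07, which became adjusted p = 0.57 with an estimated correlation. NC replicate 3 held the highest levels, with the median member 0.70 above the mean of the 6 libraries against 0.26 and 0.22 in NC replicates 1 and 2 and -0.41 to -0.34 in OPT. Without NC replicate 3 the count was again 15, with a median of -0.58, and it was 9 without OPT replicate 1 or 2. KAR2 lost its call without either of those libraries (adjusted p up to 0.0533), and HAC1 without any OPT library (up to 0.0755).

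**Figure D2:**
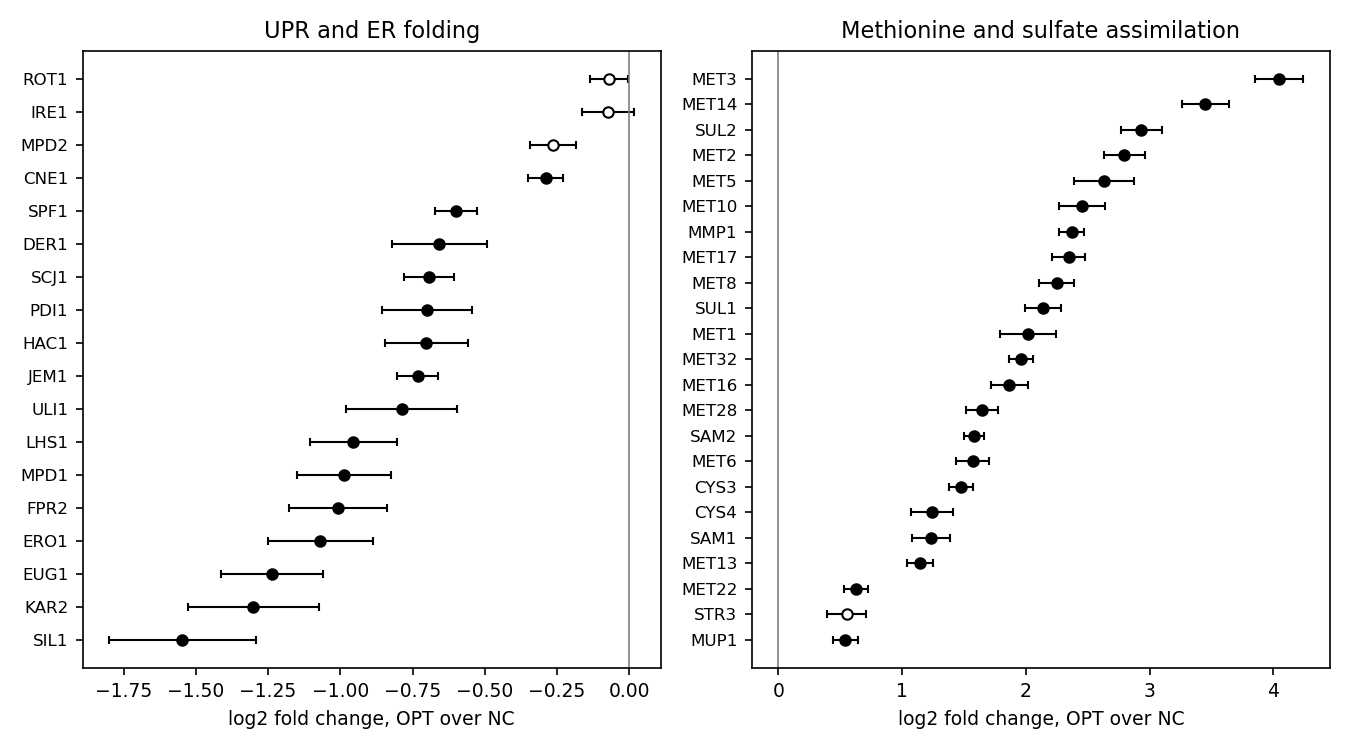
Log2 fold change, OPT over NC (x axis), of each tested gene of the ER folding list (left) and of the methionine and sulfate list (right), with bars for the standard error of the limma fit over 3 NC and 3 OPT libraries. Filled points passed an adjusted p of 0.05. In the left panel 15 of 18 genes are filled and lie below 0, and in the right panel 22 of 23 are filled and lie above 0.

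Part of the genes that bring proteins to the ER membrane also fell. In the list of signal recognition particle, translocon, GET and EMC subunits, 20 of 32 genes fell and none rose (24 fell and 1 rose when adjusted over the list alone), with a median of -0.32. SEC66, of the Sec63 complex, fell from 167 ± 8.34 to 103 ± 2.50 RPKM, PHO88 from 722 ± 68.6 to 472 ± 7.04 and GET3, the ATPase that delivers tail-anchored proteins, from 327 ± 29.9 to 217 ± 6.91. The camera adjusted p was 8.84e-07, and the adjusted p was 0.44 with an estimated correlation. The count fell to 12 once the library medians were set equal and to 5 and 10 without OPT replicates 2 and 3. Lists for the removal of faulty proteins did not pass. Of 18 genes of ER-associated degradation, 2 fell (DFM1 and DER1, log2 fold changes -0.71 and -0.66) and none rose (camera adjusted p = 0.367). Of 32 proteasome genes only PRE5 fell, at -0.29 (camera adjusted p = 0.367). In the list of ribosome-associated quality control, 3 of 19 genes fell, GCN1, SKI8 and HBS1, at -0.25, -0.25 and -0.22, and none did when adjusted over the list alone (camera adjusted p = 0.503). All 6 of those single calls ended without 1 of the OPT libraries (adjusted p up to 0.175). All but that of DFM1 also ended with equal library medians, with quantile normalization and without NC replicate 2. Among 26 cytosolic chaperones, HSP26 rose from 1476 ± 974 to 5226 ± 578 and SSA3 from 32.8 ± 5.15 to 64.4 ± 4.07, and the other members did not pass. The camera adjusted p of that list was 0.00293, with adjusted p = 0.647 for an estimated correlation. Without NC replicate 3, 10 of its members rose, and HSP26 lost its call without any 1 OPT library or NC replicate 1 (adjusted p up to 0.0798).

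Almost all tested genes of methionine synthesis and sulfate assimilation rose. Of 23 tested genes 22 rose and none fell (23 when adjusted over the list alone), with a median log2 fold change of 1.96. MET2, which acetylates homoserine, rose from 53.4 ± 10.9 to 374 ± 50.1 RPKM, alongside MET3, MET14 and SUL2. The camera adjusted p was 1.08e-29, and the adjusted p was 0.44 with an estimated correlation. The median member lay 1.20 to 0.69 below the mean of the 6 libraries in NC and 0.75 to 1.07 above it in OPT. Leaving out any 1 library left 21 to 23 members called. Many genes for other amino acids fell. Of 51 genes in a list of amino acid synthesis under the regulator Gcn4, 27 fell and 2 rose (35 and 2 when adjusted over the list alone), with a median of -0.49, a camera adjusted p of 3.63e-07 and an adjusted p = 0.647 with an estimated correlation. SER3, of serine synthesis, fell from 272 ± 45.7 to 133 ± 4.41, although it overlaps the noncoding SRG1 and is therefore uncertain, while its isozyme gene SER33 rose from 129 ± 10.6 to 533 ± 41.4. The 27 became 18 without OPT replicate 2 or 3.

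Genes for the translation machinery moved in different directions. Of 22 aminoacyl-tRNA synthetase genes 11 fell and none rose (16 when adjusted over the list alone), with a median of -0.31, a camera adjusted p of 3e-05 and an adjusted p = 0.647 with an estimated correlation. THS1, for threonine, fell from 209 ± 14.9 to 142 ± 8.37 RPKM and YDR341C, for arginine, from 200 ± 16.4 to 131 ± 6.01. That count was 18 without NC replicate 3, 7 with equal medians and 3 or 4 without an OPT library. Of 138 features in the cytosolic ribosomal protein list, 11 rose and 3 fell (1 and 0 when adjusted over the list alone), with RPL8A rising from 298 ± 53.9 to 584 ± 47.1 and a median of 0.23 for the list. Camera gave it an adjusted p of 2.41e-16, with adjusted p = 0.647 for an estimated correlation. Members of this list have near-identical copies, so single values are uncertain. Its share of all RPKM was 14.1, 11.3 and 11.4% in NC and 14.0, 14.5 and 14.2% in OPT, or 12.3 ± 1.57% and 14.2 ± 0.213% (exact permutation p = 0.2, two-sided, smallest possible 0.1). Without NC replicate 1, 89 members rose, 2 rose without NC replicate 2 and 1 or 2 without an OPT library. Of 67 ribosome biogenesis genes only NUG1 fell, at -0.64. Its call ended with equal medians, with quantile normalization and without NC replicate 2 or any OPT library (adjusted p up to 0.135). The ribosome biogenesis list did not pass (camera adjusted p = 0.0643). It passed without NC replicate 3 (adjusted p = 1.54e-08), without OPT replicate 2 (0.00131) and with equal medians (0.00622). Initiation factors did not pass either, with 6 of 27 lower and 1 higher (camera adjusted p = 0.124), TIF1 falling from 490 ± 38.6 to 332 ± 14.8, although they passed without NC replicate 3 (0.00879, with 12 lower) or OPT replicate 2 (0.0375, with 2 lower). Of 13 elongation and termination factors 3 fell, SUP45, HYP2 and EFT1, at -0.42, -0.41 and -0.33 (camera adjusted p = 0.236), and none did without an OPT library. EFT1 has an identical copy and TIF1 a near-identical one, so their single values are uncertain. Of 69 mitochondrial ribosomal protein genes 4 fell and 2 rose (camera adjusted p = 0.406).

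**Figure D3:**
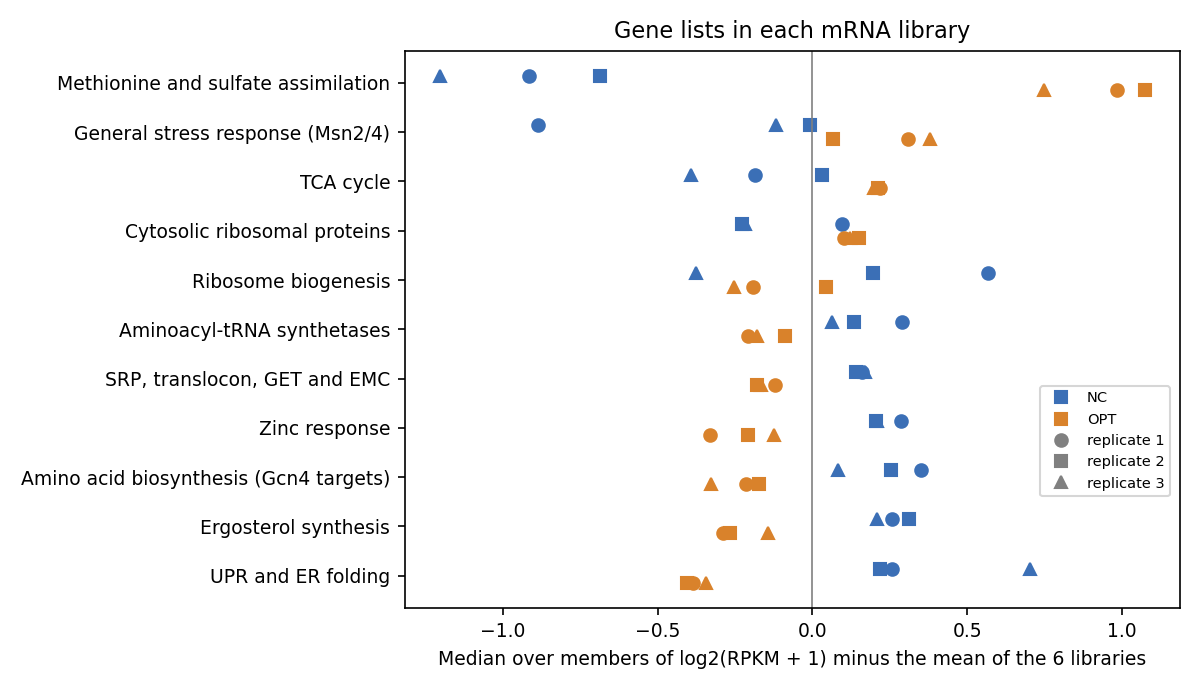
Median over the members of 11 gene lists of log2(RPKM + 1) minus the gene's mean over the 6 libraries (x axis) in each NC library (blue) and OPT library (orange), with a symbol per replicate number, which pairs no libraries. The sulfate list lies 0.75 to 1.07 above the mean in OPT. NC replicate 3 has the highest ER folding value, at 0.70, and in the ribosomal protein list NC replicate 1 lies close to the OPT libraries.

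Respiration and stress genes were higher in OPT in part. Of 18 genes of the TCA cycle 8 rose and none fell (9 when adjusted over the list alone), with a median of 0.44, among them CIT1, the mitochondrial citrate synthase, from 309 ± 63.0 to 602 ± 30.2 RPKM and SDH2, of succinate dehydrogenase, from 179 ± 29.4 to 331 ± 15.8. The camera adjusted p was 4.67e-06, and the adjusted p was 0.647 with an estimated correlation. Without any 1 OPT library 2 genes passed, and without NC replicate 1 there were 5. In the nuclear-encoded respiratory chain 2 of 36 genes rose, QCR10 and NDI1, at 0.54 and 0.39 (camera adjusted p = 1.31e-06, adjusted p = 0.647 with an estimated correlation), and 7 rose without NC replicate 2, 5 with equal medians and 0 or 1 without an OPT library. The strains overlapped in the median member of the respiratory chain list. It lay at 0.11 in NC replicate 2, above 0.08 and 0.04 in OPT replicates 2 and 3. The general stress list had 8 of 33 genes higher and none lower (9 when adjusted over the list alone), with a median of 0.48, a camera adjusted p of 3.03e-08 and an adjusted p = 0.647 with an estimated correlation. SIP18, a phospholipid-binding hydrophilin, rose from 51.6 ± 19.5 to 316 ± 18.2, and RTN2, a reticulon-like protein, from 19.4 ± 6.56 to 61.3 ± 11.5. The median member of this list lay at -0.89 in NC replicate 1 against -0.01 and -0.12 in NC replicates 2 and 3 and 0.07 to 0.38 in OPT. The count was 13 without NC replicate 3 and 4 without any 1 OPT library.

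Other lists of carbon use and nutrient limitation gave smaller counts. Of 21 genes of glycolysis and fermentation 4 rose and none fell (camera adjusted p = 0.000219, adjusted p = 0.585 with an estimated correlation), PDC5, PFK2 and PFK1 among them and PDC6, a minor pyruvate decarboxylase, from 20.4 ± 5.26 to 117 ± 12.7 RPKM. That count was 9 without NC replicate 3 and 2 without OPT replicate 2 or 3, where PFK2 and PFK1 were lost (adjusted p up to 0.0872). The median log2 fold change of the glycolysis and fermentation list was only 0.16 against a mean of 0.42, with PDC5 and PDC6 at 3.46 and 2.49. The stationary phase list had 5 of 19 higher and 1 lower (camera adjusted p = 0.000565, adjusted p = 0.647 with an estimated correlation), SPG1 rising from 5.95 ± 1.52 to 15.1 ± 2.31, with 1 or 2 higher without an OPT library and 9 with equal medians. In the oxidative stress list 6 of 24 rose and 2 fell (camera adjusted p = 0.00587, adjusted p = 0.647 with an estimated correlation). Its largest rises were GSH1, for glutathione synthesis, from 38.2 ± 7.43 to 112 ± 6.13 and ZWF1, of the pentose phosphate pathway, from 185 ± 37.0 to 348 ± 13.6, and without any 1 OPT library 2 members rose and none fell. Hexose transporters (1 higher and 1 lower of 16, camera adjusted p = 0.532), galactose and maltose genes (none of 15 in limma, with 3 at an unadjusted p under 0.05, 0.403, and 1 higher with equal medians or quantile normalization) and pyrimidine genes (1 higher and 3 lower of 12, 0.503) did not pass as lists. SUC2, the invertase gene of the galactose and maltose list, stood at 73.3 ± 1.39 and 72.4 ± 3.58. URA1, of pyrimidine synthesis, rose from 584 ± 54.4 to 936 ± 57.4. The lower pyrimidine genes were URA3, the marker of the plasmid, URA5 and URA6, at -0.73, -0.29 and -0.29 on the log2 scale. The calls of URA5 and URA6 ended with equal medians and without any 1 OPT library (limma adjusted p up to 0.118). The phosphate list (2 higher and 4 lower of 18, camera adjusted p = 0.758) did not pass.

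Most genes of the sterol synthesis and zinc lists were lower in OPT. Of 25 genes of ergosterol synthesis 17 fell and none rose (21 when adjusted over the list alone), with a median of -0.50, a camera adjusted p of 3.52e-09 and an adjusted p = 0.44 with an estimated correlation. ERG2, the sterol isomerase, fell from 850 ± 23.1 to 472 ± 14.9 RPKM, ERG26 from 301 ± 31.7 to 172 ± 2.48 and HMG1, an HMG-CoA reductase, from 147 ± 8.58 to 88.5 ± 4.03. The count was 10, 10 and 11 without OPT replicate 1, 2 and 3. Of 25 genes of phospholipid and fatty acid synthesis 8 fell and 1 rose (camera adjusted p = 0.0359, adjusted p = 0.647 with an estimated correlation), with OLE1, the fatty acid desaturase, falling from 813 ± 162 to 402 ± 10.2. This list did not pass without NC replicate 3 (adjusted p = 0.299) or OPT replicate 1 (0.0599), and 2 genes were lower with equal medians and 2 to 4 without an OPT library. In the zinc list 7 of 10 genes fell and none rose (8 when adjusted over the list alone), with a median of -0.48, a camera adjusted p of 0.000565 and an adjusted p = 0.57 with an estimated correlation. ZPS1 was the most abundant feature in every NC library and fell from 26340 ± 1229 to 16481 ± 1316, a call lost without 1 of 2 OPT libraries (adjusted p up to 0.0653). IZH1, a membrane protein of zinc metabolism, fell from 476 ± 23.1 to 252 ± 13.4. Without OPT replicates 1 and 2 in turn, 4 and 3 zinc genes fell. The iron list had 6 of 28 lower (camera adjusted p = 0.257), with FTR1, an iron permease, at -0.57 and FET3, its partner oxidase, at -0.55, and 10 fell without NC replicate 3, 2 or 3 without NC replicate 1 or 2 or with equal medians, and none without OPT replicate 1 or 2.

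Some genes specific to alpha cells and to mating were lower in OPT. Of 5 alpha-specific genes 3 fell (camera adjusted p = 0.00987, adjusted p = 0.647 with an estimated correlation), MF(ALPHA)1, the alpha-factor pheromone gene, from 3581 ± 277 to 1737 ± 31.8 RPKM and STE3, the receptor gene, from 138 ± 19.1 to 82.6 ± 4.67. Without NC replicate 3 this list did not pass (adjusted p = 0.0644). Of 18 haploid-specific and pheromone response genes 9 fell and none rose (10 and 1 when adjusted over the list alone), with a median of -0.25, a camera adjusted p of 0.00646 and an adjusted p = 0.44 with an estimated correlation. HO, the mating-type switching endonuclease, fell from 130 ± 24.0 to 71.7 ± 1.85, and 5 genes fell without OPT replicate 2 or 3. Of 7 a-specific genes only AGA2 rose, from 3.91 ± 0.730 to 6.47 ± 0.851, at a low level (3 genes rose when adjusted over the list alone). The AGA2 call ended without any 1 OPT library or NC replicate 2 (adjusted p up to 0.131). That list's camera adjusted p of 0.0423 became adjusted p = 0.57 with an estimated correlation and was lost with equal medians and without NC replicate 2 or 3 or OPT replicate 1 or 3 (0.0562 to 0.103). Of 25 cell cycle genes 7 fell (camera adjusted p = 0.0423, adjusted p = 0.769 with an estimated correlation), CLB6, an S-phase cyclin, from 18.6 ± 1.57 to 11.8 ± 0.502. The list was lost without NC replicate 1 (0.202), NC replicate 2 (0.058) or OPT replicate 1 (0.14), and 11 genes fell without NC replicate 3, with 2 or 3 without NC replicate 2 or an OPT library.

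Some lists did not pass as a whole. They were cell wall genes (1 higher and 3 lower of 24, camera adjusted p = 0.478), genes of endocytic and vacuolar turnover (1 higher of 28, 0.532), plasma membrane transporters (2 higher and 4 lower of 28, 0.848), and meiosis genes (1 higher and 5 lower of 19, 0.257). Among their members PMA2, a minor proton pump, rose from 33.5 ± 6.84 to 80.2 ± 9.59 RPKM, and SPS100, a spore wall gene, from 16.4 ± 3.12 to 100 ± 26.6. None of 10 histone genes passed in limma, with 1 at an unadjusted p under 0.05 (camera adjusted p = 0.257), and HHF1, whose values are shared with a near-identical copy, stood at 3436 ± 204 and 3323 ± 131. With quantile normalization 4 of the 10 were lower, HHT1 (limma adjusted p = 0.0112) and HHF1 (0.0377) among them, and the median of the list was -0.27 against -0.14. Of 61 tRNA features, which an mRNA library measures poorly, 4 were higher and 1 lower (0.09, and 0.0395 without NC replicate 3). The list meant for Ty elements, with 17 higher and 20 lower of 185 (0.131), also holds other small open reading frames and is not interpreted. A single mitochondrially encoded gene was tested, OLI1, at 0.697 ± 0.520 and 2.46 ± 2.45 (adjusted p = 0.453). No list call held with an estimated correlation, where the smallest adjusted p was 0.44 and 4 lists had an unadjusted p under 0.05. The median, the mean and the direction of the test differed in sign for the pyrimidine, phosphate, endocytic, mitochondrial ribosomal and Ty lists, none of which passed. The p-values compare libraries that differ in plasmid, and nothing in the labels says whether the strains were grown, extracted and sequenced side by side.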

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

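The test on protein-coding genes only was chosen after the data were seen, and the others before. The cdt-1 difference failed the test under every alternative run, from -0.17 to 0.04, with the sign turning only without OPT replicate 1. It was -0.03 with median centring. The total of 1145 calls was 1119 with no filter on low values, 1128 with a minimum of 10 RPKM, 1147 with a pseudocount of 0.1, 1095 with a common prior variance, 1148 with protein-coding genes only, 1022 with quantile normalization, 962 with median centring and 1688 with arrayWeights. Calls lower in OPT, 823 with the settings reported, were 491 with median centring and 1262 with arrayWeights, and calls higher stayed within 308 to 471 under those alternatives. Leaving out 1 library gave 361 to 1953 calls, of which 134 to 450 were higher and 227 to 1503 lower. The smallest came without OPT replicate 2 and the largest without NC replicate 3, where 1113 of the 1145 calls were kept. Each of these fits has 1 library fewer, which does not account for the rise without NC replicate 3, and the cause was not tested. Of 39 lists 20 passed, and 20 did with a pseudocount of 0.1 and with median centring, where 1 was lost and 1 gained. Leaving out 1 library gave 17 to 22. Member counts of some lists also moved with the scaling. With quantile normalization 4 of 10 histone genes were lower, against 0 with the settings reported, 5 aminoacyl-tRNA synthetase genes were lower against 11 and 3 ribosomal protein features higher against 11. With quantile normalization or median centring alike, 1 galactose and maltose gene was higher against 0, and no gene of the proteasome or of ribosome-associated quality control was lower against 1 and 3. With an estimated correlation 0 passed in camera, with 4 at an unadjusted p under 0.05, and 8 did with fry, which tests whether a list moves one way and not whether it moves more than other genes. Those 8 were the ER folding, translocon, sulfate, ergosterol, zinc, alpha-specific, haploid-specific and cell wall lists (fry adjusted p 0.00134 to 0.0449). The cell wall list was gained, and 13 of the lists that passed in camera were lost. Of 134 named yeast genes called, 117 kept their call with median centring, 113 with quantile normalization, 111 to 132 without an NC library and 70 to 82 without an OPT library, and none reversed. No paired analysis was possible because the labels give the strains no shared replicate number. The alternatives planned for footprints and translational efficiency, the replicate block included, were not run, since footprints were not analysed here.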

Other observations

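Both gene groups in this paragraph and the genes singled out here were chosen after the data were seen. Of 25 genes for the synthesis, uptake and use of thiamine, 22 rose in OPT and none fell, with a median log2 fold change of 1.13. The group was drawn up around rises already seen, THI4 among them, so no test of the whole group is given. Without the 11 members named elsewhere or seen beforehand, 12 of 14 rose and the median was 0.65. For these 14 the camera adjusted p over 2 lists was 4.53e-11, and the adjusted p was 0.0797 with an estimated correlation, which did not pass. SNZ3, a vitamin B6 synthesis paralog, rose from 65.5 ± 10.3 to 144 ± 10.8 RPKM (SD, n = 3) and PET18 from 206 ± 38.3 to 575 ± 70.2, while THI7, the thiamine permease, stood at 499 ± 182 and 935 ± 122 and missed the threshold (limma adjusted p = 0.0575). Leaving out 1 library left 16 to 22 called. Of 62 genes of protein glycosylation and GPI anchor synthesis, 41 fell and 2 rose, with a median of -0.35. Without 7 members chosen in the same way, 35 of 55 fell and 1 rose (camera adjusted p = 3.96e-09, adjusted p = 0.0797 with an estimated correlation). SEC53, which makes mannose 1-phosphate, fell from 863 ± 121 to 472 ± 13.5, and the oligosaccharyltransferase genes WBP1 and OST2 fell by 0.58 each on the log2 scale. MNN4, of mannose phosphorylation in the Golgi, went the other way, from 26.8 ± 3.74 to 68.7 ± 5.41. The 43 calls in this group became 30 with median centring or without NC replicate 2 and 14 and 11 without OPT replicates 1 and 2.

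Further genes were singled out by size of change. RAD59, a recombination gene, rose from 20.02 ± 1.58 to 130 ± 6.69 RPKM, a log2 fold change of 2.64 that held without any 1 library (adjusted p up to 0.000647). SEO1 and GRX8, a putative permease and a glutaredoxin, rose by 2.19 and 2.26. The small open reading frame YNL277W-A, which the pattern meant for Ty elements also took, rose by 2.34 and lies 481 nucleotides from MET2. TAD2, a tRNA deaminase gene 325 nucleotides from KAR2, fell by 1.12, with adjusted p up to 0.0758 when 1 library was left out. YOR387C fell from 11191 ± 1062 to 5454 ± 265.

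The tests in the rest of this part were chosen after the result was seen. Of the 10 splits of the 6 libraries into 3 and 3, only 1, the real one, called as many as 1145 genes, and the highest of the others called 0. Every other split held libraries of both strains on each side. Differences between the strains then add to the spread within a side, which makes few calls likely in advance. With 10 splits the share can also never be under 0.05, so the splits cannot settle the question of chance.

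ER folding genes were lower in OPT, and a biologist may ask whether 1 library or the scaling made it so. Without NC replicate 3, the library with the highest values, 15 of 18 members were still called lower. That fit called more features lower in all, 1503 against 823, and the median fall of the list was smaller. With the library medians set equal, 12 members were called lower. These counts argue against NC replicate 3 alone or the scaling as the whole cause. They do not cover the other libraries, and fewer members were called lower without OPT replicate 1 or 2. Slower growth of the OPT cultures stays open: 0 of the 3 OPT libraries lay below all NC libraries in the median ribosome biogenesis gene, but the NC libraries spread so widely in it, from -0.38 to 0.57, that they cover the OPT range of -0.25 to 0.04. The codon version of cdt-1, as the design names it, is untested as a cause and cannot be told apart from any other difference between the 2 sets of cultures. A higher load of misfolded protein in the ER of NC cells is a hypothesis that was not tested. The share of spliced HAC1 mRNA or a reporter of the unfolded protein response in both strains would bear on it, and neither was analysed here.

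Sulfate and thiamine genes were higher in OPT. Reads shared between THI5, THI11, THI12 and THI13 could move signal from one copy to another, but the sum over the 4 copies rose from 354 ± 136 to 2292 ± 228 RPKM, a log2 difference of 2.78, which argues against this for those genes. A difference in medium or culture batch cannot be told apart from the plasmid, because the labels give no batch that holds both strains. The median sulfate gene varied by at most 0.52 within a strain, against a median log2 fold change of 1.96 between them. No such range was computed for the thiamine genes. Among these, THI4 stood at 565, 587 and 236 RPKM in NC replicates 1, 2 and 3 and at 6487, 6194 and 6018 in OPT replicates 1, 2 and 3. The codon version of cdt-1 remains open too, as does a difference between the transformed clones, and neither was tested.

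The camera call of the ribosomal protein list may come from differences among the NC libraries. In mean log2 level, 1 of the 3 NC libraries, replicate 1 at 9.77, lay at or above the lowest OPT library, also 9.77, while NC replicates 2 and 3 stood at 9.46 and 9.42. The values are thus consistent with a list that varies between cultures of one strain. An effect of the codon version was not excluded. Other lists that passed also overlapped between the strains in their median member. For glycolysis and for cytosolic chaperones, NC replicate 3 lay at 0.10, above OPT replicates 1 and 2. For oxidative stress and for the respiratory chain, NC replicate 2 lay at 0.14 and 0.11, above OPT replicates 2 and 3. In the cell cycle list NC replicate 3, at -0.09, lay below OPT replicate 3, at -0.03.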
